A study of Mus musculus with 6 samples.

How the data were processed

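DNA methylation was measured by enhanced reduced representation bisulfite sequencing (eRRBS), which reads CpG-rich restriction fragments of bisulfite-converted DNA. The DNA came from 3 bone marrow cell types of male C57BL/6 mice aged 7 to 10 months. Long-term haematopoietic stem cells (LT-HSC), short-term haematopoietic stem cells (ST-HSC) and multipotent progenitors (MPP) were sorted from marrow pooled from 6 mice per group, per the labels' protocols. One genotype, called KI here, carried a knock-in allele of Idh1 switched on by Cre under the blood-cell promoter Vav. The other, called Control, consisted of littermates with Cre and without that allele. Each of the 6 combinations of genotype and cell type was 1 library, so no group had a replicate and no p-value below comes from replicate pools of mice.

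Per the labels' protocols, 10 ng of DNA went into each library, fragments of 150 to 400 bp were cut from a gel, and 5 libraries were sequenced per lane with 30% PhiX on a HiSeq2000. Bismark 0.10.0, SAMtools 1.0 and methylKit 0.9.1 with the mouse build mm10 are named per the submitters' processing notes. Their settings, the removal of duplicate reads and the bisulfite conversion rate are not given in the sources used here. The deposited coverage is a count of reads per cytosine position, and each library held positions with at least 10 reads. The deposited methylation values are percent of reads with C and with T, per the file headers. Coverage times percent C gave whole numbers of methylated reads at 100% of positions, within a tolerance of 0.01% of the coverage, and these numbers of reads were used in the tests. The lane numbers in the deposited names showed no lane with libraries of both genotypes, so lane and genotype cannot be told apart.

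Coverage summed to between 38284759 and 53884467 reads per library, with medians of 27 to 45 reads per position. Of 1352372 positions seen in any library, 552338 were covered in all 6 and are called shared positions. Both strands of a CpG were kept apart. Read counts overstate the precision where they hold amplified copies of 1 molecule, and whether such copies were removed is not given. At CpGs read on both strands and at 20 to 80%, the disagreement between strands corresponded to 3.27 to 7.68 independent molecules per position. In each cell type the Control library had fewer than the KI library. All intervals on reads therefore cover counting error only.

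Mean levels were unweighted over shared positions, with 95% intervals from 1000 resamplings of blocks of 1 Mb, which cover the choice of sites. Per CpG, the reads of 2 libraries were compared with a two-sided Fisher exact test and Benjamini-Hochberg adjustment. A CpG was called at an adjusted p under 0.01 and a difference of at least 25 percentage points. Such a call compares the 2 libraries, not the conditions. Windows of 1 kb with at least 5 shared positions (25123 windows) were fitted with limma 3.58.1 in R 4.3.3 on the log2 ratio of methylated to unmethylated reads with a prior count of 1. Cell type was a block, the variance had a trend, and windows were called at an adjusted p under 0.05. That test covers the spread between cell types and libraries. Whether the 3 cell types of a genotype came from 1 pool or from pools of different mice is not given in the sources used here, so how far it covers the spread between mice is not known.

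Gene coordinates came from a RefSeq table of assembly GRCm38.p6, the same build as mm10, which gave no strand. The planned promoter region could therefore not be placed. In its place stood the CpG-rich gene end, reaching from 1000 bases outside to 500 bases inside the end of a gene with at least 5 shared positions and at least 3 times those of its other end. This end was picked from positions alone and is not known to be the transcription start. Gene extents include predicted transcripts. Of 34614 protein-coding and lncRNA genes, 11461 had such an end and 414 were left out because both ends were similar. Gene ends were called with the Fisher test on summed reads at an adjusted p under 0.01 and a difference of at least 10 points in the mean of CpG levels. Exons, introns, CpG islands and sequence were not analysed here.

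Before the data were examined, 10 gene lists, the tests, the alternatives and the rule for naming genes were set. Named were Atm, Idh1, Idh2, Tet1, Tet2, Tet3, Dnmt1, Dnmt3a, Dnmt3b, Cdkn2a and Meis1 where measured. Named too were, per cell type, up to 5 called gene ends with the largest rise and 5 with the largest fall that differed in 1 direction in all 3 cell types. List members called in any cell type, up to 4 per list, and the 5 windows with the largest rise and fall completed the rule. Because fewer than 5 windows were called, the windows were taken from those at least 10 points apart in 1 direction in all 3 cell types. List medians were placed among 10000 random lists of the same size, matched on deciles of mean level. Agreement between cell types was given as Pearson r across windows, which are not independent replicates.

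The alternatives were coverage minimums of 20 and 30, summed strands, removal of positions above the 99.9th percentile, thinning to 10 reads, other size thresholds, autosomes only, other window and gene end sizes, at least 10 CpGs, a prior count of 0.5, percent values in place of log ratios, no block and each cell type left out. Centring on weakly methylated windows, calls on both strands and all alternatives for the same-direction windows were added after seeing the data. A test on the Hoxa cluster was also set up after its genes had been seen, and it was dropped as a test because those genes had prompted it. The interval of the imprinted windows was changed after its value was seen, from resampling windows to resampling loci of 1 Mb, and its decision rule was left as written.

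The scripts ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, numba 0.67.0 and matplotlib 3.10.9, and were tested on simulated data. For KI against Control in LT-HSC, with 735437 CpGs simulated as independent reads and 200 of them raised by 40 points, 25.5% of those were called and 0 unchanged CpGs were. With 6 molecules per library in place of independent reads, 29695 unchanged CpGs were called, more than the 17811 called in the real pair. In ST-HSC the same setting called 34821 unchanged CpGs against 5622 in the real pair, and in MPP 38751 against 33745. This setting thus called more CpGs than the data did, and it does not give the share of real calls that is due to sampling. For the windows by genotype, 25123 windows were simulated with 50 at each shift. With variances drawn from the limma prior, 2% of windows shifted by 2 log2 units, 60% of those shifted by 4 and 88% of those shifted by 6 were called, against 2 unchanged windows. With each window's own estimated variance, which holds estimation noise, 0% were called at every shift.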

Results

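The 6 libraries covered LT-HSC, ST-HSC and MPP of Control and Idh1 KI mice, 1 library for each genotype and cell type. The Control LT-HSC, ST-HSC and MPP libraries held 48966606, 39461301 and 44752796 reads, counted as coverage summed over CpG positions. The KI libraries held 53884467, 38284759 and 51951665 reads in the same order. IDH1 makes 2-oxoglutarate, the cofactor of the TET enzymes that oxidise methylated cytosine, and the comparisons ask how the knock-in allele and the step from stem cell to progenitor go with DNA methylation. There were no replicate libraries, so every difference below is between single libraries of pooled marrow.

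In the unweighted mean over shared CpG positions, methylation was higher in KI than in Control in all 3 cell types, and the difference per position was largest at partly methylated CpGs. Over 552338 shared positions, the mean level was 21.8% in Control and 22.0% in KI LT-HSC, a difference of 0.201 percentage points (95% block interval 0.157 to 0.241). The difference was 1.27 points in ST-HSC (1.22 to 1.32) and 1.51 points in MPP (1.46 to 1.56). At positions at 20 to 80% in the other cell types, KI was higher by 2.34 points in LT-HSC (2.02 to 2.64), 7.44 points in ST-HSC (7.03 to 7.80) and 5.82 points in MPP (5.41 to 6.18). At positions over 80%, the differences were 0.379, 1.01 and 0.916 points in the same order. Under 20%, LT-HSC stood at -0.0572 points, ST-HSC at 0.728 and MPP at 1.24. The sign of the means depended on the set of positions and their weights. Weighted by reads, KI minus Control was -4.11 points in LT-HSC and -0.564 in ST-HSC, and over all positions of each library it was -6.87 in LT-HSC.

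**Figure D1:**
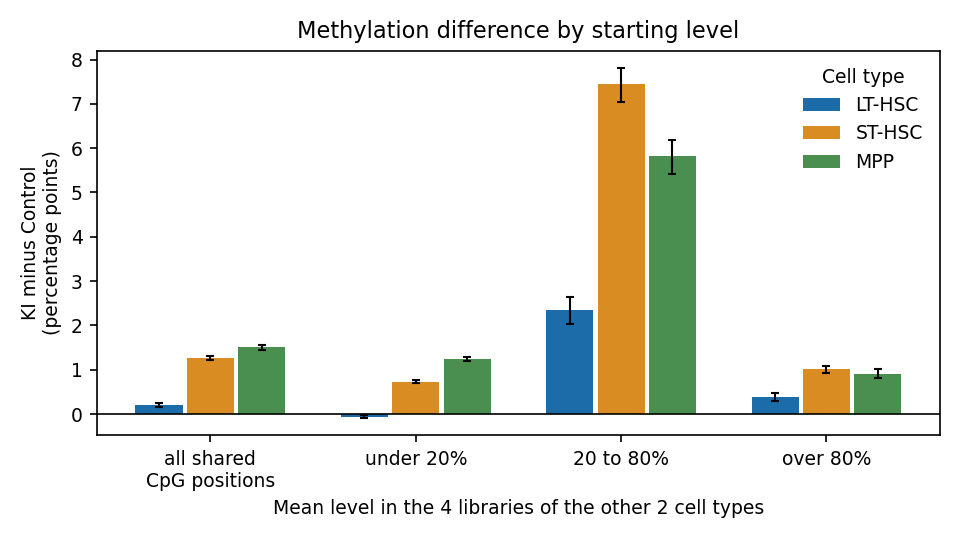
KI minus Control methylation in percentage points (y axis) for all shared positions and for 3 ranges of the mean level in the other 2 cell types (x axis), with 1 bar per cell type. Error bars are 95% intervals from resampled 1 Mb blocks and cover the choice of sites, not mice; the highest bar is ST-HSC at 20 to 80%, at 7.44 points.

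At the scale of 1 kb windows, the rises recurred across cell types far more often than the falls. Of 25123 windows, 225 were at least 10 points higher and 13 at least 10 points lower in KI in all 3 cell types. Rises of this size also outnumbered falls within each cell type, with 945 against 409 windows in LT-HSC, 1274 against 167 in ST-HSC and 1367 against 437 in MPP. The excess of recurring rises thus partly restates that imbalance, and the numbers expected from it were not computed for windows. The windows with the largest mean rise lay at an end of 2810410L24Rik (42.3 points) and in the gene bodies of Spred2, an inhibitor of Ras to MAPK signalling (42.0), Dedd2 (40.5), Anp32a (39.3) and Tapt1 (38.5). In Spred2, on chromosome 11 from 19965001 to 19966000, the level went from 10.6% in Control to 51.6% in KI LT-HSC, from 24.6 to 85.2% in ST-HSC and from 43.8 to 68.3% in MPP, over 6 positions. Lower in KI were 2 adjacent windows at the lncRNA gene Gm51701, and windows at LOC115486519, at Asb4, and on chromosome 9 from 36568001 to 36569000, nearest to Pate8 (mean difference -21.9 points).

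After the genotype labels of 1 cell type were exchanged, 32 windows (LT-HSC), 9 (ST-HSC) and 32 (MPP) were 10 points apart in 1 direction, against 238 as labelled. The excess of rises within each cell type lowers these counts by itself. With limma, 2 of 25123 windows passed, both at Gm51701 and both lower, with log2 differences of -6.20 (SE 0.36, adjusted p 0.00974) and -4.76 (SE 0.35, adjusted p 0.0258). At an unadjusted p under 0.05 there were 1755 windows. Other splits of the 6 libraries into 3 and 3 gave 413 to 3310 windows at that threshold. Without the LT-HSC libraries, 0 windows passed. Among windows with at least 10 CpGs, 3 passed as higher and 1 as lower, and at a coverage of at least 20 there were 1 higher and 2 lower windows. None of the 5 windows with the largest rise passed, the lowest adjusted p being 0.151 at 2810410L24Rik.

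**Figure D2:**
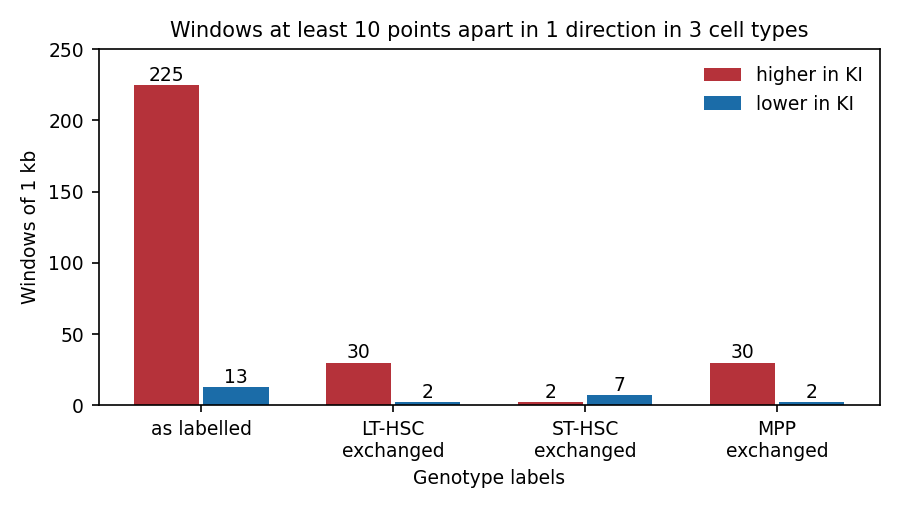
Number of 1 kb windows (y axis) at least 10 points higher or lower in KI in all 3 cell types, with the labels as given and with the labels of 1 cell type exchanged (x axis). As labelled there were 225 higher and 13 lower windows, and after each exchange at most 32 in total.

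At gene ends, too, more were called higher than lower in KI. In LT-HSC, 119 gene ends were higher and 62 lower in KI, in ST-HSC 182 and 29, and in MPP 210 and 72, of 11461 tested with the Fisher exact test. With a threshold of 5 points, LT-HSC had 313 higher and 271 lower ends, close to even, and with at least 10 CpGs it had 50 and 9. Over all 11461 ends, the mean difference in LT-HSC was -0.0746 points and the median -0.171. In all 3 cell types 31 were higher and 3 lower, and the higher ones include Gm33250 and Evpl, whose ends share the same positions. Among the 738 ends at 10 to 90%, 30 were higher and 3 lower in all 3, and the product of the shares gave 4.10 and 0.0298. Each count fell by over 1.5 times when every position was thinned to 10 reads, to 33, 62 and 89 calls.

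Rfx8, a member of the RFX transcription factor family, rose from 6.50 to 35.2% in LT-HSC, from 9.87 to 41.4% in ST-HSC and from 6.18 to 55.2% in MPP. Its measured end lies on chromosome 1 from 39720490 to 39721989 and held 23 positions with 818 to 1881 summed reads. The mean rise was 36.5 ± 11.0 points (SD over the 3 cell types, which are not replicates). Ifitm1, an interferon-induced membrane protein, rose from 30.8 to 60.8% in LT-HSC, from 33.0 to 55.0% in ST-HSC and from 17.0 to 58.4% in MPP, on 155 to 358 reads. The beta-tubulin gene Tubb4a rose by 14.9, 49.3 and 24.2 points. The lncRNA genes Gm32822, Gm10561 and Gm42060 rose by means of 42.1, 38.2 and 22.4 points, and the end of Gm10561 shares bases with that of Mars2. With 2000 bases outside the gene, the mean difference of Gm10561 was 3.49 points. LOC115490409, a lncRNA gene in the Hoxa cluster, rose by 22.3, 43.7 and 29.4 points. Acot11, an acyl-CoA thioesterase, rose in ST-HSC (45.2 points) and MPP (19.5) and differed by 2.35 points in LT-HSC. Gm34476 rose in ST-HSC (13.4) and MPP (37.1) and differed by 1.57 points in LT-HSC. Cd164l2 rose in LT-HSC (32.6), with 162 reads in KI, and was 9.93 points higher in ST-HSC and 12.0 in MPP, neither called.

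Gm51701 showed the largest fall. On chromosome 9 from 123924148 to 123925647, its level was 63.0, 57.4 and 66.9% in Control LT-HSC, ST-HSC and MPP and 2.27, 2.62 and 2.76% in KI. Pooled over the reads of this end, the KI LT-HSC share was 2.18% (Wilson 95% interval 1.60 to 2.98) and the Control share 61.6% (60.6 to 62.6). The end of Gm51701 held 8736, 7414 and 6379 reads in Control LT-HSC, ST-HSC and MPP. In KI it held fewer, at 1740, 1846 and 1736 in the same order. The cause of this difference in reads was not tested. Asb4 fell from 44.2 to 3.76%, from 40.9 to 6.05% and from 24.3 to 9.38%. LOC115486519 fell by a mean of 32.0 points, which rests on 5 positions. Rab10os fell in ST-HSC and MPP (-27.6 and -33.5 points) and differed by -9.88 points in LT-HSC, short of the 10 points for a call. Pooled over reads, it went from 33.2 to 14.2% in LT-HSC, from 24.3 to 10.7% in ST-HSC and from 37.6 to 11.2% in MPP. Ptpn20, a tyrosine phosphatase, fell in LT-HSC and MPP (-12.9 and -27.2). Falls in 1 cell type were called for the homeobox gene Alx1 in MPP (-31.9), Gm38699 in ST-HSC (-16.1), and Gm17266 (-15.6) and Tonsl (-14.2), a DNA repair gene, in LT-HSC. Pooled over reads, Alx1 in MPP fell less, from 26.5% in Control to 12.9% in KI, and its end shares bases with that of Gm34298. As a mean of CpG levels, Alx1 in Control stood at 12.9% in LT-HSC, 7.19% in ST-HSC and 44.9% in MPP.

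**Figure D3:**
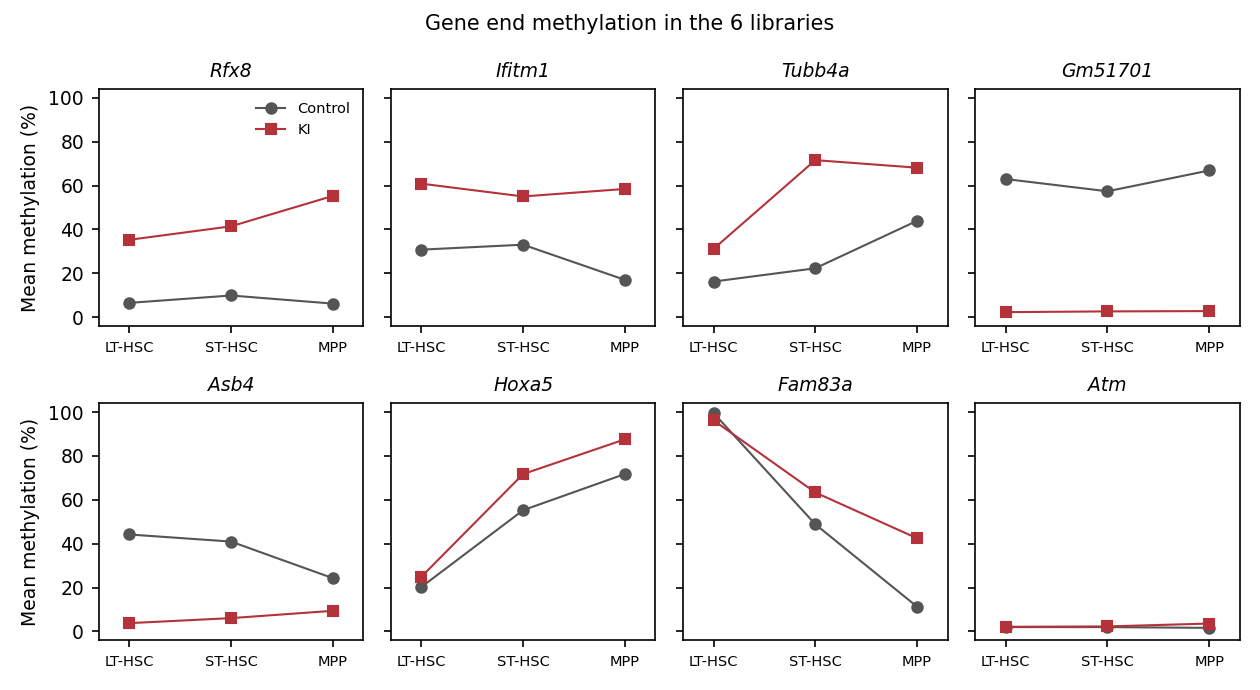
Mean methylation in percent (y axis) of 8 gene ends in LT-HSC, ST-HSC and MPP (x axis), with 1 point per library, for Control (circles) and KI (squares). Rfx8, Ifitm1 and Tubb4a were higher and Gm51701 and Asb4 lower in KI, Hoxa5 and Fam83a moved with cell type, and Atm was between 1.61 and 3.57% in every library.

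None of the measured genes named in advance was called in any cell type, because every difference was too small for a call. On the adjusted p of the Fisher test alone, Tet2 passed in ST-HSC and MPP, and Cdkn2a in MPP. Tet2 rose in MPP from 0% in Control to 4.52% in KI (adjusted p 1.79e-15). It differed by -1.58 points in ST-HSC (adjusted p 0.00853) and by -1.54 in LT-HSC (0.0176, not passing). Cdkn2a differed by 1.44 points in MPP (adjusted p 1.41e-05). These p-values cover counting error only. Atm, a kinase of the DNA damage response, was at 1.97, 1.95 and 1.61% in Control and 2.09, 2.26 and 3.57% in KI, over 18 positions, and its end shares bases with that of Npat. The mean KI minus Control difference was 0.80 ± 1.01 points (SD over cell types) for Atm, 1.02 ± 0.34 for Idh1, 0.63 ± 0.63 for Tet1, 0.47 ± 3.51 for Tet2, -0.33 ± 2.40 for Tet3, 0.35 ± 0.51 for Dnmt3b, 0.92 ± 0.56 for Cdkn2a and 0.19 ± 1.65 for Meis1. The ends of Idh1, Cdkn2a and Meis1 share bases with those of Pikfyve, Gm12610 and Gm16141. The ends of Idh2, Dnmt1 and Dnmt3a were not analysed here, since the rule for gene ends left them out.

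The lists of blood-related genes held no called member. Over all 11461 gene ends only 181, 211 and 282 were called in LT-HSC, ST-HSC and MPP, so lists this small could hold none at that rate. An end under 10% also cannot fall by 10 points, and the HSC list had a mean level of 2.69%. No call was made among all 20 measured DNA damage response genes (median difference 0.549 points, percentile 70.6 among random lists), 12 HSC genes (0.701, 82.4, and 0.336, 34.4 at a coverage of at least 20), 4 myeloid genes (0.223, 27.6), 10 lymphoid genes (0.557, 47.7) and 5 erythroid and megakaryocyte genes (0.0595, 24.99). For the last list the mean was -0.604, of the opposite sign. Of 18 methylation and IDH genes (0.670, 79.98), Kdm6b, a histone demethylase, was the called one. Of 5 endothelial and stromal genes (0.803, 59.9), the bone transcription factor Sp7 fell in MPP, from 49.4 to 18.3%, and was 7.72 points higher in LT-HSC and 9.66 in ST-HSC, neither called. The Control level of Sp7 was 6.76% in LT-HSC and 11.9% in ST-HSC, so its fall rests on the high Control MPP library. The 22 tumour suppressor and WNT inhibitor genes had a median of 1.11 points at percentile 97.2, inside the central 95% of random lists. Among them Dkk3 (21.9 points, ST-HSC) and the WNT antagonist Sfrp5 (10.6 points, MPP) rose. Dkk3 differed by 3.12 points in LT-HSC and 7.82 in MPP, and Sfrp5 by -2.88 in LT-HSC and -3.14 in ST-HSC, none of them called. Thinned to 10 reads, the mean difference of Dkk3 over cell types went from 10.9 to 5 points.

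Of 14 imprinted genes (2.94, percentile 83.9; 0.350 and 18.1 at a coverage of at least 20), 2 were higher and 2 lower in LT-HSC, 2 and 1 in ST-HSC, and 3 and 2 in MPP. The higher ones in MPP include Peg10 and Sgce, which share 1 end and are not separate measurements. Nap1l5 rose in LT-HSC (39.5) and ST-HSC (24.6) and was at -20.6 points in MPP without a call (adjusted p 0.217). Peg10 rose in MPP (28.5), and Peg3, whose end shares bases with that of Usp29, fell in ST-HSC (-25.6). Zrsr1 fell in LT-HSC (-19.0) and rose in ST-HSC (19.1) over the 18 positions of its end, but the window with 6 of them, on chromosome 11 from 22971001 to 22972000, rose in all 3 cell types, by 21.1, 29.0 and 31.6 points. Of 10 germline genes (2.21, percentile 57.6; 0.105 and 11.8 at a coverage of at least 20), Ddx4 rose in LT-HSC (14.7), Rpl10l in MPP (14.1) and Tdrd1 in ST-HSC (21.6), and Tdrd1 fell in MPP (-12.3). Adjusted over the list alone, the calls per list and cell type were equal in number for every list except the imprinted one in ST-HSC, where there were 4 against 3.

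At single CpGs, KI LT-HSC differed from Control at 17811 of 735437 positions (8709 higher, 9102 lower), ST-HSC at 5622 of 845570 (4667 higher, 955 lower) and MPP at 33745 of 841593 (21712 higher, 12033 lower). The share of higher calls was 48.9, 83.0 and 64.3%. At 78150 CpGs read on both strands in all libraries, the calls on the forward strand were 1.84, 0.456 and 2.48% of CpGs. Comparing both strands of 1 library in the same way called 3.16, 1.05 and 4.77% in the Control LT-HSC, ST-HSC and MPP libraries and 1.59, 0.614 and 1.12% in the KI libraries. The genotype calls thus lay below the strand differences within the Control library in each cell type, and in LT-HSC and MPP above those within the KI library. Called on both strands in 1 direction were 92 higher and 31 lower CpGs in LT-HSC, 47 and 4 in ST-HSC and 148 and 42 in MPP. Called in opposite directions on the 2 strands were 30, 0 and 71 CpGs in the same order. Thinned to 10 reads, 0 CpGs were called in each cell type.

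From LT-HSC to MPP, a set of gene ends that included Hoxa5 was called higher in both genotypes, and a smaller set was called lower. These genes were chosen after their values were seen. Hoxa5, a homeobox transcription factor on chromosome 6 from 52204088 to 52205587, stood at 20.2, 55.2 and 71.7% in Control LT-HSC, ST-HSC and MPP and at 24.9, 71.7 and 87.6% in KI. LOC115490409 and 5730596B20Rik in the same cluster were higher in MPP by means of 41.2 and 39.8 points. Lhcgr, the luteinizing hormone receptor, was higher by 36.2, the homeobox genes Cdx1 and Hoxd12 by 13.4 and 12.9, and the tight junction gene Cldn5 by 17.6. In the other direction, Fam83a went from 99.6 to 48.8 to 11.3% in Control and from 96.2 to 63.3 to 42.4% in KI. Tspoap1, Zfp575 and Taar4 were lower in MPP by means of -42.2, -28.9 and -19.9 points.

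In Control 184 gene ends were higher and 111 lower in MPP than in LT-HSC, and in KI 136 and 25. Called in both genotypes were 38 higher and 6 lower ends, where Gm29773 and Acta1 share the same positions. Opposite calls numbered 1 end higher in Control and lower in KI and 13 ends lower in Control and higher in KI, more than the shared falls. Among the 738 ends at 10 to 90%, 35 were higher and 6 lower in both, against 16.5 and 1.51 for independent lists, and 1 and 11 were opposite, against 2.73 and 9.16. Of the 25123 windows, 355 were at least 10 points higher and 91 lower in MPP in both genotypes, and 40 and 108 were opposite in the same order. No library is shared between these comparisons. Per CpG, 42837 of 762453 positions were called in Control (22755 higher) and 9893 of 769555 in KI (7351 higher). On both strands, 198 CpGs were called higher, 71 lower and 150 in opposite directions in Control, and 103, 11 and 11 in KI. The strand disagreement corresponded to 4.31 and 3.27 independent molecules per position in Control LT-HSC and MPP, against 5.47 and 7.68 in KI. The larger number of calls in Control therefore cannot be read as more cell type differences there. With limma over both genotypes 0 of 25123 windows passed, with 1870 at an unadjusted p under 0.05, and 8 passed, all higher in MPP, among windows with at least 10 CpGs. Over shared positions, MPP minus LT-HSC was 0.0788 points in Control (0.0287 to 0.131) and 1.38 in KI (1.34 to 1.43). Weighted by reads, the direction in Control turned, with 21.3% in LT-HSC and 20.7% in MPP, and KI stood at 17.2 and 22.2%. Over all positions of each library, the levels were 31.98 and 32.1% in Control and 25.1 and 35.1% in KI.

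The genotype differences of windows went together across cell types to a limited extent. Across 25123 windows, which are not independent, Pearson r was 0.299 for LT-HSC and ST-HSC, 0.147 for LT-HSC and MPP and 0.292 for ST-HSC and MPP. Windows moved in the same direction in 51.5, 50.1 and 56.8% of cases. Among the 3596 windows at 10 to 90% these shares were 62.3, 57.0 and 64.2%. KI was higher in 63.9% of these windows in LT-HSC, 78.0% in ST-HSC and 66.5% in MPP. This excess of rises lifts the shares by itself, and the shares expected from it were not computed. The mean KI minus Control differences of these windows were 3.39 points in LT-HSC, 6.79 in ST-HSC and 4.91 in MPP. The MPP minus LT-HSC difference of Control went with that of KI at r = 0.290.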

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

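The test of bisulfite conversion below was chosen after the result was seen. Weakly methylated CpGs differed in direction between cell types, and this difference between cell types was itself not tested. At positions under 20% in the other cell types, KI minus Control was -0.0572 points in LT-HSC, 0.728 in ST-HSC and 1.24 in MPP. At positions read as 0 in all libraries of the other cell types it was -0.115, 0.0629 and 0.511 points. If unconverted cytosines in the KI MPP library were the cause, CpGs at 5 to 20% would rise no more than CpGs at 0, yet they rose 5.99 times as much (95% interval 5.50 to 6.53), which argues against it as the whole cause in MPP. Lane cannot be told apart from genotype, and how the libraries were grouped in preparation is not given in the sources used here. Both stay open, as does an untested effect of the knock-in allele. The LT-HSC value at positions under 20% turned to 0.0267 points when positions were grouped by all 6 libraries.

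For 3 gene ends from the fixed lists the calls had opposite directions in different cell types, and none of these differences was tested. Zrsr1, an imprinted gene, was -19.0 points in LT-HSC and 19.1 in ST-HSC over 18 positions, but the window with 6 of these positions was 21.1 points in LT-HSC, 29.0 in ST-HSC and 31.6 in MPP, so its sign in LT-HSC depended on the positions taken. Kdm6b was 12.8 points in LT-HSC, 20.5 in ST-HSC and -17.3 in MPP. Its level in LT-HSC, ST-HSC and MPP was 24.8, 29.1 and 60.9% in Control and 37.6, 49.6 and 43.6% in KI. The opposite sign in MPP thus goes with the high level of 1 library, Control MPP. That library had the fewest independent molecules per position (3.27). Tdrd1 was 21.6 points in ST-HSC and -12.3 in MPP.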

How the results depend on the processing

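Calls on both strands, centring, and all alternatives for the same-direction windows were chosen after seeing the data. Of 149 alternatives of the main results, 92 stayed within 1.5 times the count or within the interval, or kept their side of the limits, and 7 changed sign. Coverage of at least 30 gave 10894, 20393, 23761 and 6385 called CpGs for KI against Control in LT-HSC and MPP and for MPP against LT-HSC in Control and KI, with fewer positions tested. Thinning to 10 reads gave 0 in the 3 genotype comparisons, 1583 for MPP against LT-HSC in Control and 0 in KI, where depth is the limit. A threshold of 10 points gave 29652 in LT-HSC and 15452 for KI MPP against LT-HSC. Calls on both strands were 123, 51 and 190 in LT-HSC, ST-HSC and MPP. The mean difference in LT-HSC changed sign over all positions of each library (-6.87) and weighted by reads (-4.11), and that in ST-HSC weighted by reads (-0.564). It was 1.21 in ST-HSC at coverage 20, and 2.16 (ST-HSC) and 2.95 (MPP) over all positions. Windows by genotype numbered 0 on percent values, 4 with at least 10 CpGs (3 higher, 1 lower), and 0 to 2 when each cell type was left out in turn. MPP against LT-HSC gave 8 windows with at least 10 CpGs. It could not be fitted without 1 genotype, which leaves no residual degrees of freedom. Gene ends with at least 10 CpGs numbered 59, 108 and 108 in LT-HSC, ST-HSC and MPP, thinned ones 33, 62 and 89, and those at 5 points 584 (313 higher, 271 lower in LT-HSC), 461 and 986. Coverage 20 gave 130 in ST-HSC. Agreement (r) with at least 10 CpGs was 0.390, 0.246 and 0.372 for LT-HSC with ST-HSC, LT-HSC with MPP and ST-HSC with MPP, and 0.352, 0.215 and 0.355 at coverage 20. Same-direction windows numbered 145 at coverage 20, 83 with at least 10 CpGs, 556 without LT-HSC, 385 without ST-HSC and 464 without MPP. Under 20%, LT-HSC was -0.0862 at coverage 20 and changed sign, to 0.0267, when grouped by all 6 libraries. So grouped, the values were 0.195, 0.880 and 0.333 over 80% in LT-HSC, ST-HSC and MPP, 7.97 (ST-HSC) and 4.09 (MPP) at 20 to 80%, and 1.54 in MPP under 20%. LT-HSC over 80% was 0.485 at coverage 20. The erythroid and megakaryocyte median changed sign at 2000 bases (-0.173), as a mean (-0.604) and at coverage 20 (-0.405), and so did Tet1 (-0.235), Tet3 (0.952) and Tdrd1 (-0.713) at coverage 20. Gm10561 was 3.49 points with 2000 bases outside the gene and Dnmt3b 0.946 at coverage 20. The cause was not tested for any of these unless named. All other list alternatives kept their sign and their side of the limits, but several values moved by over 1.5 times. At coverage 20 the medians were 0.350 (imprinted, percentile 18.1), 0.105 (germline, 11.8), 0.336 (HSC), 0.330 (lymphoid), 0.432 (myeloid) and 0.285 (endothelial and stromal). At 2000 bases they were 0.899 (lymphoid) and 0.108 (endothelial and stromal), and as a mean 0.0283 (myeloid) and 1.46 (endothelial and stromal).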

Other observations

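Tests on bisulfite conversion, on sampling of few molecules and on linkage to Idh1, and the set of windows lower in MPP in both genotypes, were chosen after the results were seen. Among the 33 windows at least 20 points higher in KI in all 3 cell types, the 6 named next were picked after their values were seen, without a test for any gene group. The mean difference was 24.8 points over 36 positions at Mn1, a transcriptional coregulator rearranged in leukaemia, 33.3 points over 26 positions at Def6, a lymphocyte signalling protein, and 35.6 points over 10 positions at Bcl6b, a transcriptional repressor. Windows at the transcription factor genes Nfix (37.5 points) and Mef2d (34.5 points) and at Dmtn, a red cell membrane skeleton gene (23.7 points), were in the same set. Of the 225 windows at least 10 points higher, 11.6% were intergenic (7.69 to 16.5, exact binomial interval), against 20.9% of windows at 10 to 90% and 10.9% of all windows. In gene bodies lay 46.2% (39.6 to 53.0), against 39.7 and 27.6%.

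The Hoxa cluster was looked at because Hoxa4 and Hoxa5 had been seen first, and it had the highest mean and the lowest median of the 4 Hox clusters. Its 25 windows had a mean KI minus Control difference of 5.27 points and a median of 0.730, with 0.986 in LT-HSC, 9.31 in ST-HSC and 5.50 in MPP. The means were 2.56 points in Hoxb, 2.32 in Hoxc and 1.91 in Hoxd, and the medians 1.25, 2.39 and 1.94. In LT-HSC, Hoxa was below Hoxb (1.23) and Hoxc (1.16). At 1 window of Hoxa4, on chromosome 6 from 52191001 to 52192000, the level was 5.11, 5.74 and 9.01% in Control and 20.99, 38.0 and 39.2% in KI, while the adjacent window of Hoxa4, with 13 positions, differed by -12.1 points in LT-HSC, -15.1 in ST-HSC and 1.32 in MPP.

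The rise at partly methylated windows in 3 cell types was weighed against technical causes. Sampling of few molecules, if equal in both genotypes, would leave as many windows in 1 direction after an exchange of labels. At most 32 were left of 238. Sampling was not equal, with 4.31, 6.05 and 3.27 independent molecules per position in Control LT-HSC, ST-HSC and MPP. In KI there were 5.47, 7.00 and 7.68. The effect of this inequality on rises and falls was not tested, so the exchange cannot decide on sampling, which stays open. Because rises outnumbered falls in each cell type, an exchange lowers the count even if different windows rose in each. The count thus bears on the excess of rises and cannot show that the same windows recur. Unconverted cytosines would raise unmethylated CpGs by at least 50% of the partly methylated rise, and the highest ratio was 0.0879. More MPP-type cells in the KI gates, as the whole cause, would lower windows that are lower in Control MPP, yet in ST-HSC their median difference was 2.63 points (2.09 to 3.47, 827 windows), and 5.93 (3.80 to 13.3) for the 91 lower in both genotypes; the 1186 windows higher in Control MPP had 5.19 (4.52 to 5.90), which leaves such cells open as part of the rise. Amplification bias towards methylated molecules stays open: 23 imprinted windows at 30 to 70% had a median of 0.409 points (-2.15 to 4.56 over 14 loci) against 7.10 (6.26 to 8.02) elsewhere, but the upper bound lay above 3.55, the limit set in advance. An effect of the knock-in allele may underlie the rise but cannot be told apart from lane. Library preparation stays open too, since its grouping is not given in the sources used here.

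At the 36 windows at least 20 points apart in 1 direction in all 3 cell types, variants between the pools of mice may be a cause. In 100% of these windows (at least 90.3%, exact binomial bound) 50% or more of the positions were 20 points apart, so the differences were not confined to a few positions. The windows were selected on these same differences, which favours a high share. Both strands of a CpG also count as separate positions, and the bound treats adjacent windows as independent. No conclusion on variants at single CpGs is therefore drawn. Variants carried along with the Idh1 locus that act on nearby windows are argued against as the whole cause, since 86.1% of the windows, 31 of 36 (70.5 to 95.3), lay on other chromosomes; they stay open for the 2 windows within 20 Mb of Idh1 (5.56% of the 36, 0.680 to 18.7, against 1.19% of all windows), too few to decide. The 6 libraries allow 10 splits, too few for a share under 0.05. Only 1, the split by genotype, called any windows with limma (2 windows, both lower at Gm51701, highest other 0). This count bears on those 2 windows and not on the rises. With cell type as a block, splits that part the libraries of only 1 cell type compare the genotypes within it. The other splits are therefore not all equal regroupings. At an unadjusted limma p under 0.05, the genotype split gave 1755 windows. The other splits that part the libraries of all 3 cell types gave 758 to 1243, and those that part only 1 gave 413 to 3310. A variant that sets the methylation of a whole region, as at Gm51701, was not tested, nor was an effect of the knock-in allele at these windows.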
